A study of Mus musculus with 38 samples.

How the data were processed

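RNA from whole bone marrow was measured on an Affymetrix GeneChip whole-genome mouse array, with biotin as the label and 1 colour, in 38 mice and 1 array per mouse. Per the labels, progenitors expressing c-kit were transduced with a retrovirus carrying 1 of 5 MLL fusion oncogenes and transplanted into lethally irradiated syngeneic male or female recipients. Marrow cells were harvested at euthanasia and cryopreserved, and RNA was extracted with Trizol. Leukaemic mice are named here by cohort and the number in their label. The deposited table holds 1 linear intensity per probe set and array, which the authors scaled before deposit: the mean after trimming 2% at each end was 500 on every array. All intensities were above 0, no detection calls were used, and the software behind the values is not given in the sources used here. No column of values was left unused.

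Of 45101 probe sets, 64 are controls, 34958 carry exactly 1 gene symbol in the annotation used, 932 carry several and 9211 carry none there. Of those with 1 symbol 34754 were matched by Entrez identifier to a RefSeq gene table, which changed 0 symbols. Probe sets with several symbols or none were not assigned to genes. Values were converted to log2(intensity + 46.1), where 46.1 is the 25th percentile of all values. The medians of the arrays spanned 0.537 on this scale, above the limit of 0.5 set in advance, so each array was shifted to the same median. A probe set was kept when it exceeded its array's median on at least 4 arrays, the size of the smallest group. This kept 29004 probe sets, 23902 of them with 1 symbol, for 13333 genes. Where a gene had more than 1 kept probe set (6007 genes) the one with the highest mean over all arrays stood for the gene. Fold changes are ratios on the log2(intensity + pseudocount) scale, which understates changes of dim genes. A fold change describes the mean of the mice in a group, and the number of mice, not of probes, limits its precision. Standard errors are those of limma and SD is between mice.

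Comparisons were fitted with limma 3.58.1 in R 4.3.3 as 1 linear model of 6 group means with moderated 2-sided tests (32 residual degrees of freedom, 36.93 with the prior). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were the unweighted mean of the 5 cohorts against normal marrow, each cohort against normal, each cohort against the mean of the other 4, an F test among the 5 cohorts, and the 3 cohorts with a nuclear fusion partner against the 2 with a cytoplasmic one. The nuclear and cytoplasmic division came from general knowledge of the partner proteins, as did the 27 gene lists, which were fixed before the data were examined except that 1 list, the stem cell maintenance genes, was chosen by the study. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists, and again with an estimated correlation and with fry. The counts of genes of a list called over all genes are given beside the counts adjusted over the list alone. Where both are equal the text says on both counts. In the leukaemia comparison fry called 20 of the lists, camera 18, and camera with an estimated correlation 9. Against the other cohorts the same 3 tests, in that order, called 2, 6 and 0 lists in MLL-AF1p, 1, 10 and 1 in MLL-AF10, 8, 10 and 3 in MLL-GAS7, 2, 7 and 2 in MLL-AF9 and 6, 13 and 0 in MLL-ENL, and 6, 12 and 0 for the nuclear partners. How many mice showed a difference was counted against the median of the normal samples or of the other cohorts, and where the text says beyond all normal samples, against their range.

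Genes named in the text followed a rule written before the data were examined. For leukaemia against normal these were the 10 largest rises and 10 largest falls among called genes with the same sign in all 5 cohorts. For each cohort against the others they were the 4 largest rises and 4 largest falls called, and for nuclear against cytoplasmic partners the 5 largest of each. From each list up to 4 called members with the largest change were eligible, and any member of a list of at most 10 genes. Predicted genes and clone names were counted but not named. Quality signs were compared between leukaemia and normal by an exact permutation test over all 73815 splits of the 38 arrays into 34 and 4, adjusted over the 4 signs. They were the 3' to 5' ratios of actin and Gapdh control probe sets, 18S signal and the mean of 9 hybridisation control probe sets.

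The effect of sharing the 4 normal samples was measured with 100 simulations of unchanged cohorts and with all 6 splits of the normal samples into 2 pairs. The pipeline was tested on simulated data with 13333 genes. Each gene's mean over all arrays received normal noise with the gene's moderated SD, drawn independently for every gene and array. With changes of 1.5-fold, 2-fold and 4-fold, the comparison of leukaemia with normal called 32.8%, 79.1% and 100% of the changed genes, with 6 false calls among 147. The comparison of MLL-GAS7 with the others called 44.8%, 94.0% and 100%, with 7 false among 166. The 1 list shifted was found each time, and 0 of 19 other lists were called.

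Alternatives fixed in advance were values as deposited, quantile normalization, no filter, the mean of the probe sets of a gene, leaving out probe sets of the types that may read several transcripts or genes, the 5th percentile (7.6) or the median (157.2) as pseudocount, an added 2-fold limit, a trended and robust prior, array weights, only the arrays of the groups compared, all 34 leukaemias as 1 group, an estimated correlation for lists, and leaving out each array in turn. After the data were examined 2 sets of arrays were found. For 16573 probe sets of genes with several, each probe set's deviation from its gene's mean was taken, and 1791 of them defined a score per array, computed without the array itself. The set as a term, only set 1, only set 2, leaving out 5 arrays with a mean hybridisation control signal above 12.25 (log2), and leaving out genes of the X and Y chromosomes were then added as alternatives. Those 5 arrays were MLL-GAS7_410 (13.2), MLL-AF1p_803 (12.9), MLL-AF10_798A (12.9), MLL-GAS7_407 (12.5) and normal mouse 3 (12.5). For lists within array sets the text gives the mean change of the members less that of all genes. Random draws used seed 1. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. The probe sets without a symbol and the fusion transcripts were not analysed here.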

Results

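Gene expression was measured in whole bone marrow of 38 mice, with 1 Affymetrix oligonucleotide array per mouse. Leukaemia had been started in 34 of the mice with a retrovirus that carried 1 of 5 MLL fusion oncogenes. In such a fusion the front part of MLL (mouse gene Kmt2a), a histone methyltransferase, is joined to a partner protein. The virus was put into marrow progenitor cells bearing the c-kit receptor, which were then transplanted into irradiated C57BL/6 recipients of either sex, and marrow was taken at euthanasia. The oncogene was MLL-AF1p in 9 mice, MLL-AF10 in 8, MLL-ENL in 7, and MLL-GAS7 and MLL-AF9 in 5 each, and 4 normal marrow samples served as controls. The deposited intensities of 45101 probe sets had the same trimmed mean of 500 on every array. The median intensity per array ran from 129.2 to 208.3 over all 38 arrays and from 160.1 to 184.9 over the normal arrays. After filtering, 13333 genes were compared on the log2(intensity + 46.1) scale. On the first principal component, which held 25.6% of the variance, the normal samples lay between 75.85 and 87.24 and the leukaemias between -22.22 and 24.21.

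**Figure D1:**
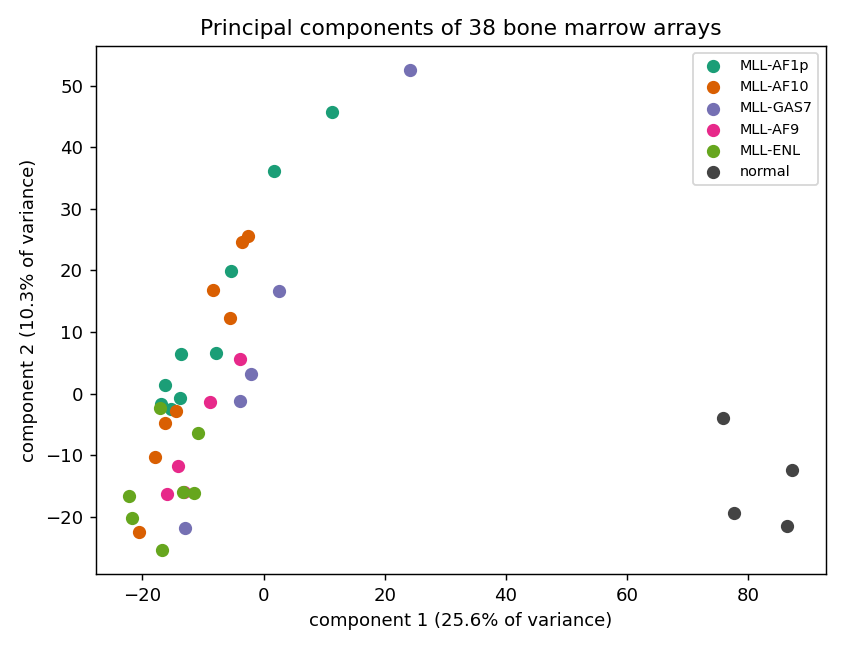
Each point is the array of 1 mouse, placed by its first principal component (horizontal, 25.6% of variance) and its second (vertical, 10.3% of variance), coloured by cohort. The 4 normal samples lie apart from all 34 leukaemias on the first component, while the 5 cohorts overlap on both.

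The first comparison asked what the leukaemic marrows shared against normal marrow. The homeobox gene Hoxa9, a known target of MLL fusion proteins that holds progenitors in self-renewal, rose from 7.78 ± 0.36 (log2, SD, n = 4) in normal marrow to between 12.14 and 13.07 in the 5 cohorts. The mean rise was 4.95 ± 0.21 (SE), or 31.0-fold, with adjusted p = 7.27e-21 by limma. Meis1, the DNA-binding partner of Hoxa9, rose 13-fold (3.70 ± 0.25, adjusted p = 4.94e-15), from 6.74 ± 0.65 (n = 4) in normal marrow. Both genes lay above all 4 normal samples in 34 of 34 leukaemias. Alas2, the enzyme that starts haem synthesis in red cell precursors, dropped by 8.64 ± 0.18 (400-fold, adjusted p = 3.33e-31), from 14.70 ± 0.27 (n = 4) to between 5.79 and 6.38. The other largest rises common to all 5 cohorts were those of the X-inactivation RNA Xist (40.9-fold), the transcription factor Mycn (39.1-fold), the apolipoprotein Apoc2 (30.6-fold), the bicarbonate transporter Slc4a8 (26.7-fold), the endocytosis adaptor Sgip1 (23.2-fold), the prostaglandin dehydrogenase Hpgd (22.2-fold), Tctex1d1 (17.2-fold) and the enkephalin precursor Penk (14.3-fold). The Mycn rise rested on 1 probe set: another kept Mycn probe set fell by 0.91 (adjusted p = 0.00973). The other largest falls were those of the carbonic anhydrases Car2 (198-fold) and Car1 (63.1-fold), the red cell anion exchanger Slc4a1 (173-fold), Hemgn (170-fold), Tent5c (161-fold), the platelet chemokine Ppbp (79.9-fold), the Rh-associated glycoprotein Rhag (69.1-fold), Tspan33 (66.8-fold) and Tmcc2 (63.1-fold). In 34 of 34 leukaemias each of these genes lay beyond all 4 normal samples, except Xist, which did so in 32. In MLL-AF9 the Xist rise was 4.29-fold, with 4 of 5 mice at 8.74 to 10.66 and MLL-AF9_305 at 14.67 (log2), and it belongs to the sex-linked pattern described further on. With only the 18 leukaemias and 4 normal samples of the second array set described further on, all 20 of these genes kept their call.

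Among the 17 MLL fusion targets measured, 13 were higher and 0 lower, and 14 and 0 when adjusted over the list alone. Their median log2 change was 1.89 (camera adjusted p = 2.06e-07, and 0.00119 with an estimated correlation). They included the developmental regulators Hoxa10 (9.68-fold, adjusted p = 1e-11) and Eya1 (8.52-fold, adjusted p = 5.72e-05), above the normal median in 34 and 32 of 34 leukaemias. None of the 4 measured HoxB genes was called, over all genes or adjusted over the list alone. Hoxb2 moved by 0.04, Hoxb3 by -0.13, Hoxb4 by -0.22 and Hoxb7 by -0.28, with a camera adjusted p of 0.438 for the list. Changes under 2-fold may have been missed. Of MLL and the genes of its partners, Mllt10, which encodes AF10, rose 1.62-fold (adjusted p = 0.00019). Mllt1 (ENL) rose 1.90-fold (adjusted p = 0.00832), though its adjusted p was 0.124 without normal mouse 3 and 0.0578 without the 5 arrays with the brightest hybridisation controls. Mllt3 (AF9) fell 4.36-fold (adjusted p = 4.12e-07) and Eps15 (AF1p) 1.54-fold (adjusted p = 0.00317). Kmt2a (-0.20, adjusted p = 0.202) and Gas7 (0.39, adjusted p = 0.357) were not called, although Kmt2a was with the values as deposited (-0.33, adjusted p = 0.0293) and after quantile normalization (adjusted p = 0.0239). Mllt10 lay above the normal median in 33 of 34 leukaemias, Mllt1 in 31, and Mllt3 and Eps15 below it in 34. The list of 6, with 2 higher and 2 lower on both counts, had a median of 0.10, which was -0.03 with the values as deposited, and a mean of -0.15 (adjusted p = 0.44). These probe sets read the mouse genes, and the fusion transcripts were not analysed here. The study is known for work on the stem cell maintenance genes Myb, Hmgb3 and Cbx5, a choice made on these samples, so their values are not independent evidence. The progenitor transcription factor Myb rose 2.03-fold (adjusted p = 3.13e-06), the chromatin protein Hmgb3 fell 2.99-fold (adjusted p = 1.22e-05), and Cbx5, a heterochromatin protein, was not called (-0.20, adjusted p = 0.366), except after quantile normalization (-0.39, adjusted p = 0.0233). Myb lay above the normal median in 32 of 34 leukaemias and Hmgb3 below it in 34. The list of 3 gave adjusted p = 0.597, with 1 higher and 1 lower also when adjusted over the list alone.

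Gene lists of most other lineages shifted down. Of 22 erythroid genes, 19 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median of -4.62 (adjusted p = 2.33e-40, and 1.26e-10 with an estimated correlation). All 21 B cell genes were lower on both counts, with a median of -2.63 (adjusted p = 1.55e-26, and 3.07e-05 estimated). The recombinase gene Rag1 fell 22.8-fold, the coactivator Pou2af1 19-fold, the receptor chain Cd79a 17.7-fold and the adaptor Blnk 13.7-fold. Of 12 megakaryocyte and platelet genes 11 were lower on both counts (median -2.03, adjusted p = 8.86e-15, and 1.77e-06 estimated), led after Ppbp by Pf4 (23.5-fold), Tubb1 (10-fold) and Clec1b (8.86-fold). Resident macrophage genes were lower in 12 of 16 on both counts (median -1.76, adjusted p = 5.39e-09, and 0.00504 estimated). The complement genes C1qa and C1qc fell 17.9-fold and 11.5-fold, the mannose receptor Mrc1 6.79-fold and Cd5l 6.70-fold. Genes of eosinophils, basophils and mast cells were lower in 6 of 10 and higher in 1 on both counts (median -2.06, adjusted p = 6.51e-05, and 0.0342 estimated). The granule proteins Prg2 (51.3-fold), Epx (45.9-fold) and Prg3 (10.4-fold) and the IgE receptor Fcer1a (4.34-fold) fell most. T and NK cell genes were lower in 11 of 16 (12 adjusted over the list alone, median -0.93, adjusted p = 3.01e-06, and 0.00891 estimated), including Cd3d (6.20-fold), Nkg7 (2.84-fold), Cd2 (2.71-fold) and Klrd1 (2.36-fold). Of 16 stroma, bone and endothelium genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone, median -0.60, adjusted p = 0.000145, and 0.0151 estimated). The niche chemokine Cxcl12 fell 9.56-fold, the fat hormone Adipoq 8.91-fold and the collagen gene Col1a2 2.66-fold. Of 14 haematopoietic stem cell genes 6 were lower and 2 higher (7 and 2 adjusted over the list alone, median -0.50, adjusted p = 0.000565, and 0.00255 estimated). Vwf (10.8-fold), Gfi1b (7.75-fold) and Pdzk1ip1 (7.58-fold) fell, while the progenitor marker Cd34 rose 4.03-fold (adjusted p = 0.000719). Loss of other lineages was untested as a source. Each gene named here lay on its side of the normal median in 34 of 34 leukaemias, except Prg3 and Cd34 (33), Klrd1 (32) and Nkg7 (30).

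Late neutrophil genes were lower in 11 of 18 and higher in 0 (12 and 1 adjusted over the list alone), with a median of -1.41 and adjusted p = 3.72e-05, but adjusted p = 0.351 with an estimated correlation. The secondary granule protein Ltf fell 7.01-fold, the integrin Itgb2l 6.28-fold, the chemokine receptor Cxcr2 5.64-fold and the gelatinase Mmp9 5.61-fold. Primary granule genes, which promyelocytes make earlier, were higher in 6 of 9 and lower in 0 on both counts (median 0.53), short of the threshold as a list (adjusted p = 0.0574). That list was called without a filter (adjusted p = 0.0231), with the mean of the probe sets (0.0452), without probe sets that may read more than 1 gene (0.0483), within array set 2 (0.0451) and without the 5 arrays with the brightest hybridisation controls (0.0228), and its median was 0.31 after quantile normalization. The granulocyte regulator Gfi1 rose 3.19-fold and the proteases Ctsg 2.41-fold, Prtn3 2.30-fold and Elane 1.77-fold. Elane had adjusted p = 0.0754 under quantile normalization. Monocyte genes were higher in 10 of 19 and lower in 1 on both counts, with a median of 0.65 and adjusted p = 0.0422, but adjusted p = 0.598 with an estimated correlation. That list call was also lost after quantile normalization (adjusted p = 0.0862), with the array set as a term (0.052), within set 2 (0.0713) and without MLL-AF1p_801 (0.0526), MLL-AF9_305 (0.0577), normal mouse 1 (0.0886) or normal mouse 4 (0.0686). Ms4a6c (4.66-fold), Ly86 (3.44-fold), the lysosomal protein Cd68 (2.92-fold) and the fractalkine receptor Cx3cr1 (2.91-fold) rose. Of 20 myeloid transcription factors 9 were higher and 3 lower on both counts (median 0.49, adjusted p = 0.943); Cebpa, the driver of granulocyte commitment, rose 2.64-fold and the erythroid factor Gata1 fell 13.5-fold. The 9 MHC class II genes were lower in 6 and higher in 1 on both counts (median -0.78, adjusted p = 0.00255, adjusted p = 0.285 with an estimated correlation). The invariant chain Cd74 fell 5.70-fold, H2-Aa 4.42-fold, H2-Eb1 3.27-fold and H2-Ob 3.03-fold, and H2-DMa rose 2.44-fold. Ciita, their transactivator, fell 1.67-fold (adjusted p = 0.00455). H2-Oa (-0.46) and H2-DMb2 (-0.55) were not called, and H2-Ab1 (-0.78, adjusted p = 0.0484) lost its call when 1 array was left out in 29 of the 38 cases and with the array set as a term (-0.50, adjusted p = 0.19). The called genes named here lay on their side of the normal median in 34 of 34 leukaemias, except Elane, Cebpa, H2-DMa and Ciita (33), Gfi1 and Cd74 (32), Ctsg, H2-Aa and H2-Eb1 (31) and H2-Ab1 (30).

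Ribosome and glycolysis lists shifted up while the mitosis list shifted down. Of 19 cytosolic ribosomal protein genes 16 were higher and 0 lower on both counts (median 0.53, adjusted p = 1.46e-05, adjusted p = 0.351 with an estimated correlation), with Rpl11 at 2.11-fold and Rps19 at 2.02-fold. Its median was 0.09 after quantile normalization, and the call was lost without probe sets that may read more than 1 gene (adjusted p = 0.14). Of 20 ribosome biogenesis genes 12 were higher and 0 lower (13 and 0 adjusted over the list alone, median 0.54, adjusted p = 0.0148, adjusted p = 0.608 with an estimated correlation), with Rrs1 at 2-fold and Dkc1 at 1.93-fold, and a median of 0.36 after quantile normalization. Glycolysis genes were higher in 10 of 12 and lower in 1 on both counts (median 0.75, adjusted p = 0.01, adjusted p = 0.353 with an estimated correlation). Triosephosphate isomerase Tpi1 rose 2.36-fold, Pgam1 2.23-fold, Pfkp 2.02-fold and Aldoa 1.90-fold, and the median was 0.51 after quantile normalization. Of 27 oxidative phosphorylation genes 10 were higher on both counts, among them Cycs (1.84-fold) and Uqcrc2 (1.64-fold), but the list was not called (median 0.24, and 0.03 after quantile normalization, adjusted p = 0.143). Mitosis genes were lower in 13 of 21 and higher in 0 (15 and 0 adjusted over the list alone, median -0.56, adjusted p = 1.1e-07, adjusted p = 0.29 with an estimated correlation). Ube2c fell 2.87-fold, Nusap1 2.54-fold, cyclin Ccna2 2.24-fold and survivin Birc5 2.22-fold. DNA replication genes were lower in 7 of 25 and higher in 1 on both counts (median -0.03, but -0.15 as deposited and -0.22 after quantile normalization, mean -0.17, adjusted p = 0.0299, adjusted p = 0.641 with an estimated correlation). That call was lost without MLL-AF9_305 (adjusted p = 0.0542), normal mouse 1 (0.138) or probe sets that may read more than 1 gene (0.0624). The ribonucleotide reductase subunit Rrm2 fell 2.34-fold and the licensing factor Cdc6 2.13-fold. Among 11 BCL2 family genes 3 were higher and 1 lower on both counts (median 0.34, and 0.20 after quantile normalization, adjusted p = 0.599). The survival gene Bcl2l1 fell 4.84-fold, while the death genes Pmaip1 (4.81-fold) and Bid (2.21-fold) and the survival gene Bcl2l2 (1.93-fold) rose. Interferon response genes were lower in 3 of 19 and higher in 1 (1 and 1 adjusted over the list alone, median -0.17, adjusted p = 0.0606, but 0.0487 without the 5 arrays with the brightest hybridisation controls and 0.0482 with array weights), with Rsad2 down 33.7-fold (adjusted p = 7.7e-17). Of 14 immediate early and heat shock genes 3 were higher and 2 lower on both counts. The test of that list pointed down (adjusted p = 0.597) although its median (0.25, and 0.08 after quantile normalization) and mean (0.07) were positive. Btg2 fell 2.33-fold and Dnajb1 1.98-fold, and Nr4a1 rose 1.92-fold (adjusted p = 0.00872, and 0.0573 without the 5 arrays with the brightest hybridisation controls). These genes lay on their side of the normal median in 34 of 34 leukaemias, except Rrs1, Bid, Bcl2l2 and Nr4a1 (33) and Dkc1 (32).

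**Figure D2:**
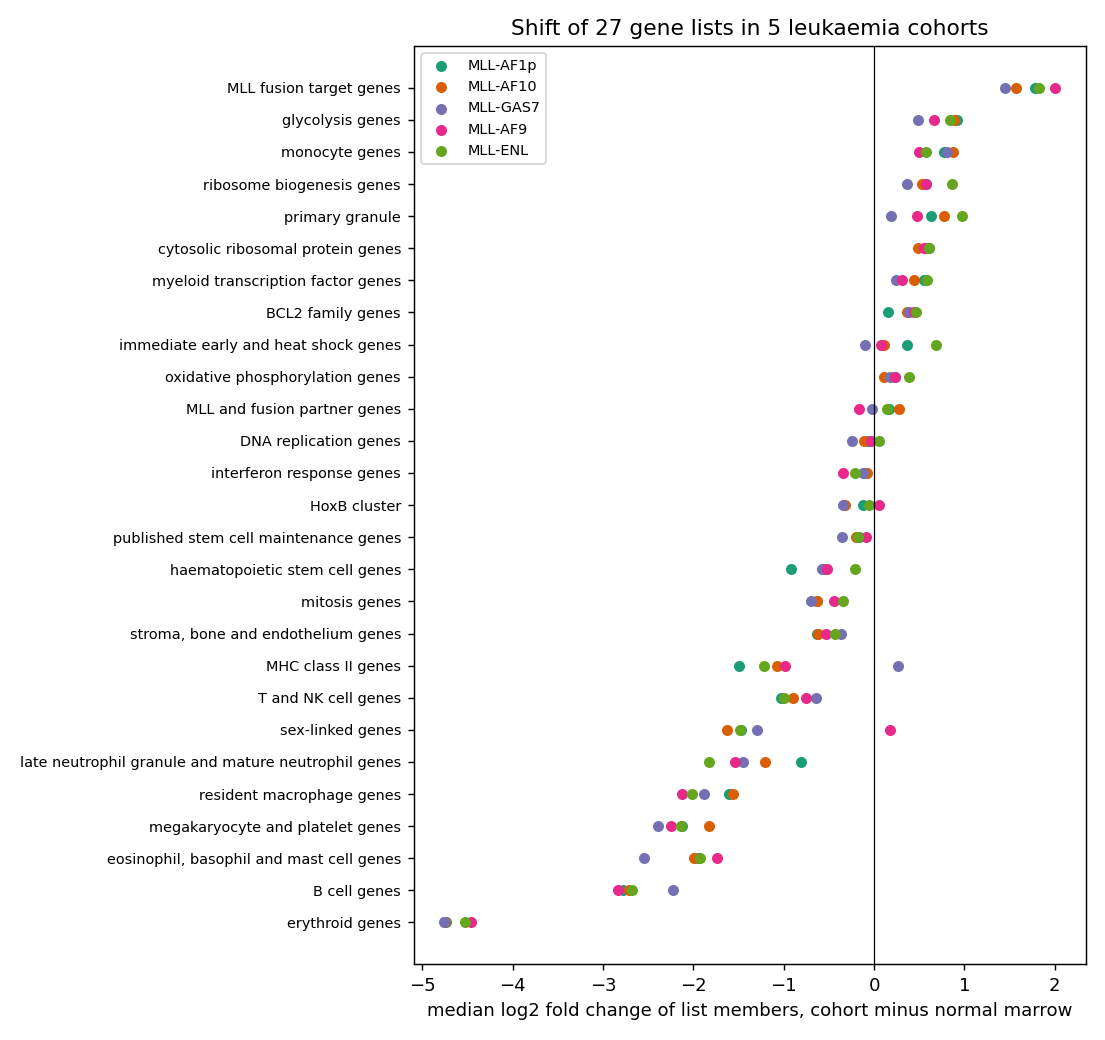
Median log2 fold change of the members of 27 gene lists (horizontal axis, cohort minus normal marrow), 1 point per cohort. The erythroid list lies lowest and the MLL fusion target list highest in each of the 5 cohorts, and the MHC class II list lies above 0 in MLL-GAS7 alone.

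In all, 5588 of 13333 genes differed between the mean of the 5 cohorts and normal marrow, 3878 higher and 1710 lower, and 1715 of them at least 2-fold. The split depended on scaling: higher genes made up 69.4% of the calls after the arrays were shifted to the same median, 57.0% with the values as deposited and 60.5% after quantile normalization. The median log2 change of all genes was 0.16, 0.04 and 0.09 in the same order. Leaving out 1 array gave between 4549 and 5902 genes. Of 4 RNA quality signs 1 differed after adjustment. The ratio of 3' to 5' actin signal averaged 0.315 (log2) in the leukaemias and 0.137 in normal marrow (difference 0.178, exact permutation p = 0.00583, adjusted 0.0233), and 18S ribosomal RNA signal 8.76 and 7.76 (log2, exact permutation p = 0.0397, adjusted 0.0794). The ratio for Gapdh (-0.273 and -0.254, exact permutation p = 0.742) and the hybridisation controls (11.6 in both, exact permutation p = 0.885) did not differ detectably.

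Each cohort was then set against the same 4 normal samples, to ask whether every oncogene gave the same picture. MLL targets were higher in each of them, 13 of 17 in MLL-AF1p, 12 in MLL-AF10, 12 in MLL-GAS7, 13 in MLL-AF9 and 11 in MLL-ENL. Of the 22 erythroid genes 19, 20, 19, 20 and 19 were lower in the same order, and of the 21 B cell genes 21, 21, 19, 21 and 21. MHC class II genes were lower in 7 of 9 in MLL-AF1p and in MLL-ENL, in 6 in MLL-AF10 and in 5 in MLL-AF9, while in MLL-GAS7 1 was higher and 1 lower (adjusted p = 0.932). Called genes numbered 4873 in MLL-AF1p, 4873 in MLL-AF10, 3613 in MLL-GAS7, 4477 in MLL-AF9 and 5523 in MLL-ENL, and higher genes made up 66.2%, 67.8%, 61.4%, 70.6% and 73.2% of them. With the values as deposited these shares were 55.3%, 56.2%, 56.7%, 58.0% and 57.0%, and after quantile normalization 58.6%, 58.6%, 58.3%, 60.2% and 60.8%. Of the 27 lists 18, 19, 15, 17 and 19 were called, and 10, 10, 8, 8 and 9 with an estimated correlation. In all 5 cohorts 1635 genes were higher and 869 lower, 2504 in total. Sharing controls alone gave at most 401 such genes in 100 simulations of unchanged cohorts, and 5 independent lists would share 9.57 higher and 0.222 lower genes. The fold changes of the 13333 genes correlated across genes, which are not independent replicates, with a mean r of 0.917 over the 10 pairs of cohorts (0.869 to 0.959). Simulated unchanged cohorts with shared controls gave 0.525 on average and 0.852 at most. With the normal samples split between the cohorts of a pair, so that no control was shared, r was 0.824.

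Whether the oncogenes differed from one another was asked next, first over all 5 cohorts and then for each cohort against the other 4. By limma's F test 1078 genes differed among the cohorts, 500 of them at least 2-fold between the highest and lowest cohort mean. The arrays themselves fell into 2 sets that the labels do not name, found from how different probe sets of the same gene read against each other, with scores at or below -0.716 in set 1 and at or above 0.408 in set 2. Set 1 held 4 MLL-AF1p, 3 MLL-AF10, 2 MLL-GAS7, 3 MLL-AF9 and 4 MLL-ENL mice. Set 2 held 5, 5, 3, 2 and 3 in the same order and all 4 normal samples, so the comparisons with normal marrow could be made within set 2 only. The F test called 1241 genes with the set as a term, 110 within set 1 and 249 within set 2. The leukaemia comparison with normal marrow called 5684 genes with the set as a term and 5757 within set 2.

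**Figure D3:**
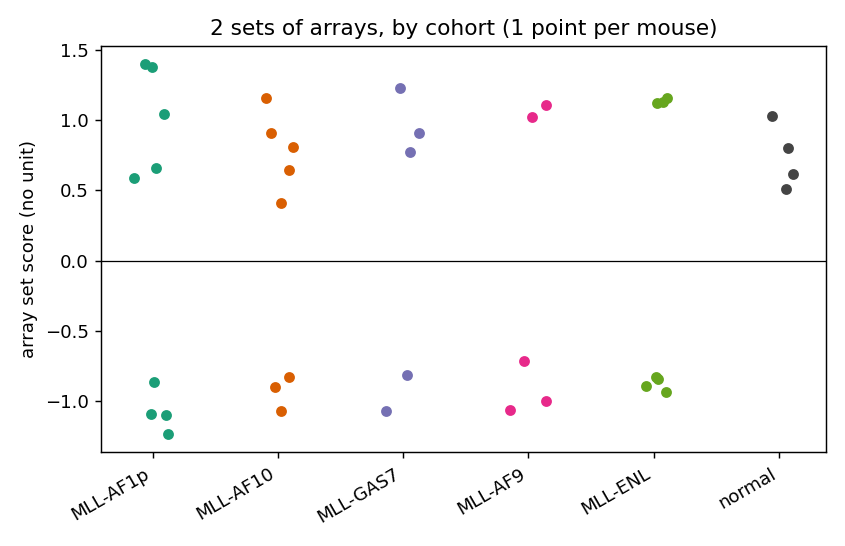
Score (vertical axis, no unit) by which the arrays fell into 2 sets, 1 point per mouse, by cohort. Each leukaemia cohort has arrays on both sides of 0, and the 4 normal samples all lie above it, at 0.509 or higher.

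Against the mean of the other cohorts, MLL-AF1p had 2 of 18 late neutrophil genes higher. The neutrophil collagenase Mmp8 was 3.30-fold higher (1.72 ± 0.33, adjusted p = 0.00245), at 13.12 ± 0.81 (log2, SD, n = 9), and above the median of the other leukaemias in 9 of 9 mice. The formyl peptide receptor Fpr2 was 2.88-fold higher (adjusted p = 0.0121, 8 of 9 mice, but 0.0501 without MLL-AF1p_803). Late neutrophil genes shifted up by a median of 0.63 (2 of 18 higher, 4 adjusted over the list alone, adjusted p = 1.66e-09, adjusted p = 0.302 with an estimated correlation). Within array sets 1 and 2 the mean shift of that list relative to all genes was 0.82 and 0.60 (adjusted p = 3.44e-13 and 0.000901). The HMG-box gene Bbx rose 4.63-fold (2.21 ± 0.19, adjusted p = 6.23e-10, and adjusted p = 0.0173 and 2.1e-05 within the 2 sets), the transcription factor Tcf24 4.91-fold and the membrane repair protein Myof 3.21-fold, each in 9 of 9 mice. The mast cell protease Cpa3 fell 4.16-fold (adjusted p = 0.0168) and the mitochondrial kinase Ak3 2.51-fold (adjusted p = 0.000113), both in 9 of 9. The lymphoid factor Ikzf2 fell 3.52-fold (8 of 9 mice), and the growth factor receptor Pdgfrb 2.50-fold, which became -0.59 (adjusted p = 0.348) without probe sets that may read more than 1 gene. MHC class II genes shifted down by a median of -0.58 (2 of 9 lower, 5 adjusted over the list alone, adjusted p = 9.63e-05, adjusted p = 0.302 with an estimated correlation), with H2-Oa 2.19-fold lower in 8 of 9 mice (adjusted p = 0.00114). The mean shift of the MHC class II list was -0.25 within array set 1, not called (adjusted p = 0.0843), and -0.79 within set 2 (2.74e-05). Primary granule (0.32, 0 of 9 called, 2 adjusted over the list alone), glycolysis (0.24, 1 of 12 higher, 3), B cell (-0.17, 3 of 21 lower, 3) and sex-linked lists were also called, with adjusted p of 0.0019, 9.63e-05, 0.036 and 0.036, and adjusted p = 0.302, 0.302, 0.614 and 0.302 with an estimated correlation. The B cell call was lost without any 1 of 10 arrays, with the highest adjusted p (0.318) without MLL-GAS7_407. It was also lost with the values as deposited (0.0599), with the array set as a term (0.0533), without probe sets that may read more than 1 gene (0.374) and without the 5 arrays with the brightest hybridisation controls (0.294). Within set 2 the primary granule and B cell lists were not called (adjusted p = 0.115 for both). The B cell gene Cd79b was 1.56-fold lower in 9 of 9 mice (adjusted p = 0.014). In total 104 genes were higher and 207 lower. The total of 311 fell to 171 without MLL-AF1p_803 and rose to 477 without MLL-GAS7_407. With the array set as a term 349 genes were called, within set 1 only 3 and within set 2 105. Of the 8 genes named by size of change, all kept their sign in both sets, 1 was called within set 1 and 5 within set 2.

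MLL-AF10 marrows stood out by Mycn, a MYC family oncogene, which reached 15.46 ± 0.34 (log2, SD, n = 8) against 11.38 to 12.14 in the other cohorts. The difference was 3.65 ± 0.23 (12.6-fold, adjusted p = 3.71e-14) in 8 of 8 mice, and 3.93 and 3.42 within array sets 1 and 2 (adjusted p = 6.03e-05 and 2.31e-08). The other kept Mycn probe set differed by 0.19 (adjusted p = 0.806), and the one that the filter left out averaged 7.02 in MLL-AF10 and 6.62 to 6.91 in the other cohorts. The sialyltransferase St3gal6 rose 3.74-fold in 8 of 8 mice (adjusted p = 2.13e-05), but by 0.03 (adjusted p = 0.978) without probe sets that may read more than 1 gene. The macrophage glycoprotein Gpnmb rose 2.79-fold in 8 of 8 (adjusted p = 0.00741). The membrane protein Ms4a6d rose 3.02-fold (adjusted p = 0.0179), with adjusted p = 0.0895, 0.107 and 0.0527 without MLL-AF10_782A, MLL-AF10_799A and MLL-AF10_798A. Spred2, a brake on Ras signalling, fell 1.83-fold in 7 of 8 mice (adjusted p = 0.00741). Tmem212 fell 1.81-fold (adjusted p = 0.0135, and 0.0522 without MLL-AF10_797A), and Trp53i11 fell 1.72-fold (adjusted p = 0.0464) but lost its call without any 1 of 26 arrays. Monocyte (0.22, adjusted p = 0.00246), resident macrophage (0.31, adjusted p = 0.0057), primary granule (0.16, adjusted p = 0.0345), megakaryocyte (0.09, adjusted p = 0.0408), glycolysis (0.09, adjusted p = 0.0272), interferon (0.14, adjusted p = 0.047) and fusion partner (0.25, adjusted p = 0.0378) lists shifted up without a called member. Oxidative phosphorylation (-0.13, adjusted p = 0.00126) and immediate early (-0.24, adjusted p = 0.0162) lists shifted down, also with none. With an estimated correlation these gave adjusted p = 0.489, 0.374, 0.489, 0.374, 0.548, 0.742, 0.374, 0.68 and 0.459 in the order named. Adjusted over the list alone, 1 resident macrophage, 2 megakaryocyte and 2 fusion partner genes were called. Single arrays carried several of these calls. Without MLL-AF10_798A adjusted p was 0.107 for fusion partner, 0.145 for primary granule, 0.124 for megakaryocyte and 0.161 for interferon genes, and without MLL-AF10_805A 0.104, 0.104, 0.119 and 0.18. The glycolysis call was lost without MLL-AF10_799A (0.111) and the immediate early call without MLL-AF10_783A (0.075). The primary granule call was lost without any 1 of 5 arrays, the megakaryocyte call of 8 and the interferon call of 15, and the interferon shift turned to -0.05 without MLL-AF10_797A. With the values as deposited and after quantile normalization neither the interferon (0.0692 and 0.0586) nor the megakaryocyte list (0.0692 and 0.0942) was called. The interferon call was also lost with the array set as a term (0.118), and the fusion partner (0.144), primary granule (0.0604) and immediate early (0.11) calls without the 5 arrays with the brightest hybridisation controls. Within array set 1 all but the glycolysis (0.413) and immediate early (0.494) lists were called, with mean shifts up to 0.53 (resident macrophage), and within set 2 only these 2 of the 9 were. Late neutrophil and ribosome biogenesis lists, not called over all arrays, went opposite ways within sets 1 and 2 (0.805 and -0.389, adjusted p = 6.05e-10 and 0.0199, and -0.352 and 0.139, 1.76e-05 and 0.0462). In all 26 genes were higher and 15 lower, 41 in total. The total was 18, 25, 14 and 24 without MLL-AF10_782A, MLL-AF10_797A, MLL-AF10_799A and MLL-AF10_798A, and 46, 7 and 4 with the array set as a term, within set 1 and within set 2. Of the 8 genes named by size, 4 were called within set 1, 2 within set 2, all with the same sign, and 5 without the arrays with the brightest controls.

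MLL-GAS7 marrows kept MHC class II expression and had fewer transcripts of promyelocyte genes. H2-Aa, which presents antigen, stood at 12.84 ± 1.23 (log2, SD, n = 5), near the 12.57 ± 0.19 (n = 4) of normal marrow, and was 8.04-fold above the other cohorts (3.01 ± 0.41, adjusted p = 2.22e-05). Cd74 was 7.13-fold, H2-Eb1 5.60-fold and H2-Ab1 3.42-fold higher, each above the median of the other leukaemias in 5 of 5 mice. Of 9 MHC class II genes 7 were higher on both counts (median 1.27, adjusted p = 2.92e-16, and 0.00424 estimated), and within array sets 1 and 2 the mean shift of the list was 0.89 and 1.98 (adjusted p = 2.46e-06 and 2.62e-15). The chromatin organiser Satb1 rose 8.28-fold (adjusted p = 0.0022, 5 of 5 mice). B cell genes shifted up (median 0.48, 3 of 21 higher, 9 adjusted over the list alone, adjusted p = 1.46e-09, and 0.0306 estimated), with Cd22 at 2.57-fold (adjusted p = 0.00191). The mean shift of that list was 0.54, and 0.81 and 0.31 within array sets 1 and 2 (adjusted p = 8.96e-12 and 0.00135), and it was 0.27 (0.0237) without the 5 arrays with the brightest hybridisation controls. Ighm was 2.72-fold higher, but 0.15 (adjusted p = 0.675) without probe sets that may read more than 1 gene. The NK receptor gene Klrd1 was 2.15-fold higher (adjusted p = 0.000668). Each of the genes named here lay on its side of that median in 5 of 5 mice. Akr1c13, an aldo-keto reductase, fell 9.91-fold (-3.31 ± 0.35, adjusted p = 1.01e-07) and the granulocyte progenitor gene Ms4a3 4.96-fold (adjusted p = 3.05e-06), both in 5 of 5 mice and called within each array set. Mgam fell 4.96-fold (adjusted p = 0.000347). The histamine-forming enzyme Hdc fell 4.57-fold (adjusted p = 0.0217), with adjusted p = 0.0896, 0.119 and 0.0912 without MLL-GAS7_405, MLL-GAS7_408 and MLL-GAS7_410. Primary granule genes were lower in 4 of 9 (8 adjusted over the list alone, median -0.66, adjusted p = 6.16e-08, and 0.0306 estimated), with Ctsg 3-fold (adjusted p = 7.47e-06) and Gfi1 2.74-fold lower (adjusted p = 0.0018, and 0.0688 without the 5 arrays with the brightest hybridisation controls). Glycolysis genes were lower in 5 of 12 (9 adjusted over the list alone, median -0.47, adjusted p = 7.76e-07, adjusted p = 0.094 with an estimated correlation), with Hk1 1.55-fold lower (adjusted p = 0.0018) but adjusted p = 0.236 as the mean of its probe sets.

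Several other lists were called in MLL-GAS7 and rested on few mice. Stroma (0.21, 2 of 16 higher and 3 adjusted over the list alone, adjusted p = 0.00134), T and NK (0.13, 1 of 16 higher on both counts, 0.00645), late neutrophil (0.41, 1 of 18 higher on both counts, 0.0137) and monocyte (0.11, 0 of 19, 0.0117) lists shifted up. Ribosome biogenesis (-0.40, 0 of 20, 0.00159) and DNA replication (-0.27, 1 of 25 lower on both counts, 0.00253) lists shifted down. With an estimated correlation adjusted p was 0.0595, 0.206, 0.618, 0.618, 0.618 and 0.618 in the order named. Without MLL-GAS7_407 adjusted p was 0.232 for stroma, 0.356 for T and NK, 0.677 for late neutrophil, 0.121 for ribosome biogenesis and 0.0797 for DNA replication genes. Without MLL-GAS7_410 it was 0.162 for late neutrophil and 0.332 for monocyte genes. None of these 6 lists was called without the 5 arrays with the brightest hybridisation controls (adjusted p = 0.191, 0.811, 0.714, 0.723, 0.636 and 0.164 in the order named). Within array set 1 the stroma list alone among them was called. The late neutrophil call was also lost with the values as deposited (0.149) and after quantile normalization (0.137), and the T and NK call after quantile normalization (0.0667). The T and NK median was 0.22 as deposited, and after quantile normalization the monocyte median was 0.20 and that of DNA replication -0.17. Of the MLL fusion targets 3 of 17 were higher and 6 lower (3 and 8 adjusted over the list alone, list adjusted p = 0.291), and Meis1 was lowest here, at 9.20 ± 0.55 (n = 5). In total 158 genes were higher and 479 lower. Higher genes made up 24.8% of the calls, but 44.2% with the values as deposited and 41.2% after quantile normalization. The total of 637 became 1131, 422, 382 and 317 without MLL-GAS7_406, MLL-GAS7_407, MLL-GAS7_408 and MLL-GAS7_410, and 244 without the 5 arrays with the brightest hybridisation controls, which include MLL-GAS7_407 and MLL-GAS7_410. With the array set as a term it was 735, within set 1 50 and within set 2 281. Of the 8 genes named by size of change, 2 were called within set 1 and 7 within set 2, all with the same sign.

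MLL-AF9 marrows differed from the others first in sex-linked genes. The Y-linked translation factor gene Eif2s3y was 19.3-fold higher (4.27 ± 0.22, adjusted p = 4.28e-17) and the Y-linked demethylase Kdm5d 3.77-fold higher, each in 5 of 5 mice, and Xist was 16.8-fold lower in 4 of 5. Of 4 sex-linked genes 3 were higher and 1 lower on both counts (adjusted p = 6.72e-09, and 8.56e-06 estimated). Inseparable from sex too, the MLL target Meis1 was highest here, at 11.39 ± 0.23 (log2, SD, n = 5), 2.26-fold above the other 4 (1.18 ± 0.23, adjusted p = 0.00554, 5 of 5 mice). MLL targets as a list shifted up by a median of 0.37 (1 of 17 higher on both counts, adjusted p = 0.000123, and 0.0219 estimated), with a mean shift of 0.26 within array set 1 (adjusted p = 0.0575) and 0.41 within set 2 (8.9e-05). The cytotoxic granule protein Nkg7 rose 4.43-fold (adjusted p = 0.000314, 5 of 5 mice) to 11.43 ± 0.58, near the 11.22 ± 0.44 of normal marrow (n = 4). The actin regulator Fnbp1l rose 3.56-fold (adjusted p = 0.000207, 4 of 5). Ms4a6d fell 3.99-fold (adjusted p = 0.008, and 0.0796 without MLL-AF9_308), and Mycn fell 2.73-fold in a comparison that contains the high MLL-AF10 cohort. The ubiquitin ligase Rnf128 fell 2.73-fold (adjusted p = 0.0267), with adjusted p = 0.107, 0.0796 and 0.188 without MLL-AF9_307, MLL-AF9_308 and MLL-AF9_305. Late neutrophil (-0.22, adjusted p = 0.000256), monocyte (-0.21, 0.00112), interferon (-0.22, 0.00314) and resident macrophage (-0.11, 0.0289) lists shifted down with no called member, each with adjusted p = 0.617 with an estimated correlation. Adjusted over the list alone, 1 late neutrophil gene was called. The monocyte call was lost without MLL-AF9_308 (adjusted p = 0.102), the interferon call without MLL-AF9_307 (0.158), and the resident macrophage call without MLL-AF9_307 (0.311), MLL-AF9_310 (0.0866) or MLL-GAS7_407 (0.0839). Within array set 2 none of the 4 was called (adjusted p = 0.713, 0.158, 0.937 and 0.119), and within set 1 all but the resident macrophage list (0.0636) were. Without the 5 arrays with the brightest hybridisation controls the late neutrophil (0.116), interferon (0.0877) and resident macrophage (0.188) calls were lost. The study's 3 stem cell maintenance genes shifted up (median 0.36, 0 called, 2 adjusted over the list alone, adjusted p = 0.0289, adjusted p = 0.445 with an estimated correlation), a call lost without MLL-AF9_301 (0.0584), MLL-AF9_308 (0.102) or MLL-AF9_310 (0.0603), and within each array set (0.0622 and 0.21). In all 39 genes were higher and 10 lower. The total of 49 became 30, 32 and 31 without MLL-AF9_308, MLL-AF9_301 and MLL-AF9_310. It was 64 with the array set as a term, 20 within set 1 and 9 within set 2, where 5 and 3 of the 8 genes named by size were called. DNA replication (0.189 and -0.236), mitosis (0.219 and -0.219) and ribosome biogenesis lists (0.224 and -0.267) were called in opposite directions within the 2 sets (adjusted p up to 0.00358).

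Against the mean of the others, MLL-ENL had 5 of 9 MHC class II and 3 of 18 late neutrophil genes lower. The small GTPase Rhoj was 4.12-fold higher than in the other cohorts (2.04 ± 0.23, adjusted p = 8.01e-07), at 10.18 ± 0.64 (log2, SD, n = 7), in 7 of 7 mice, and by 1.67 and 2.44 within array sets 1 and 2 (adjusted p = 0.0203 and 0.0012). The decoy receptor Il22ra2 rose 3.91-fold (adjusted p = 5.1e-05, 7 of 7), the ERK phosphatase Dusp6 3.02-fold (0.00218, 6 of 7) and coagulation factor F7 2.94-fold (0.0116, 7 of 7). Mmp8 fell 4.06-fold (-2.02 ± 0.36, adjusted p = 0.000864), H2-Aa 3.58-fold (0.00261) and the cytokine receptor Flt3, itself on the list of MLL targets, 3.56-fold (0.00425), each in 7 of 7 mice, and Eml5 fell 3.53-fold in 6 of 7 (0.00133). MHC class II genes were lower in 5 of 9 on both counts (median -0.79, adjusted p = 1.48e-07, adjusted p = 0.101 with an estimated correlation), and late neutrophil genes in 3 of 18 (5 adjusted over the list alone, median -0.57, adjusted p = 1.14e-07, adjusted p = 0.325 with an estimated correlation). The mean shifts of these lists were -0.64 and -0.997 within array set 1 and -1.08 and -0.58 within set 2, all 4 called. Against normal marrow the MHC class II median was -1.22 in MLL-ENL and lower still in MLL-AF1p, at -1.49. Oxidative phosphorylation (median 0.25, adjusted p = 4.7e-05), ribosome biogenesis (0.33, 0.000261), DNA replication (0.30, 0.000395) and mitosis genes (0.24, 0.00792) shifted up. The medians were smaller with the values as deposited (0.15, 0.24, 0.20 and 0.14) and after quantile normalization (0.11, 0.22, 0.18 and 0.12), where the mitosis call was lost (adjusted p = 0.0682). Members higher numbered 3 of 27, 3 of 20, 1 of 25 and 0 of 21 over all genes, and 11, 10, 11 and 0 adjusted over the list alone. With an estimated correlation these lists gave adjusted p = 0.436, 0.436, 0.493 and 0.608. The replication factor gene Rfc4 rose 1.58-fold (adjusted p = 0.0164, 7 of 7). Of 14 immediate early genes 4 were higher (7 adjusted over the list alone, adjusted p = 0.00866, adjusted p = 0.373 with an estimated correlation), with Egr1 2.66-fold higher (adjusted p = 0.000983) in 7 of 7 mice. The mean shift of that list was 0.50 within array set 1 (adjusted p = 0.000219) and 0.16 within set 2, not called (0.186). Primary granule genes were higher in 2 of 9 (3 adjusted over the list alone, adjusted p = 0.0356, adjusted p = 0.436 with an estimated correlation), with Ms4a3 2.06-fold higher (adjusted p = 0.0116, 7 of 7). That list call was lost without MLL-AF1p_801 (0.0505), MLL-GAS7_406 (0.0681) or MLL-ENL_742 (0.057) and MLL-ENL_774 (0.0728), and within set 1 (0.212).

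Monocyte genes were lower in 2 of 19 in MLL-ENL (3 adjusted over the list alone, median -0.16, adjusted p = 5.72e-05, adjusted p = 0.325 with an estimated correlation), with the pattern receptor Tlr2 2.09-fold lower in 7 of 7 mice (adjusted p = 0.000232). The mean shift of the monocyte list was -0.08 within array set 1, not called (adjusted p = 0.357), and -0.65 within set 2 (5.64e-08), and its median was -0.30 after quantile normalization. Resident macrophage (-0.30, 0.00128), T and NK (-0.11, 0.00866) and megakaryocyte genes (-0.16, 0.0378) shifted down without a called member on either count, each with adjusted p = 0.315 with an estimated correlation. The megakaryocyte call was lost without any 1 of 7 arrays, with adjusted p up to 0.0792 without MLL-ENL_760. Within set 2 none of these 3 lists was called (adjusted p = 0.0502, 0.0949 and 0.24), and after quantile normalization the T and NK (0.0983) and megakaryocyte (0.145) calls were lost, as they were without the 5 arrays with the brightest hybridisation controls (0.0686 and 0.142). As deposited their medians were -0.21 and -0.25. MLL targets showed 1 of 17 higher and 3 lower (2 and 3 adjusted over the list alone, list adjusted p = 0.0526, below the threshold without any 1 of 14 arrays and lowest at 0.0126 without MLL-ENL_742). In total 492 genes were higher and 170 lower. Higher genes made up 74.3% of the calls, but 48.7% with the values as deposited and 48.5% after quantile normalization. The total of 662 became 1168 without MLL-GAS7_406, and 417, 377, 279 and 339 without MLL-ENL_701, MLL-ENL_760, MLL-ENL_741 and MLL-ENL_703. With the array set as a term it was 761, within set 1 60 and within set 2 71. Of the 8 genes named by size of change, 3 were called within set 1 and 3 within set 2, all with the same sign.

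AF9, ENL and AF10 are nuclear proteins of transcription complexes, while AF1p (Eps15) and GAS7 are cytoplasmic, a division from general knowledge rather than the labels, so the 3 cohorts with a nuclear partner were set against the 2 with a cytoplasmic one. Fnbp1l was 3.08-fold higher with a nuclear partner (1.62 ± 0.21, adjusted p = 2.03e-05), above the median of the cytoplasmic cohorts in 20 of 20 mice, and by 1.39 and 1.90 within array sets 1 and 2 (adjusted p = 0.2 and 0.000437). The lactosylceramide synthase B4galt6 was 2.32-fold higher (1.21 ± 0.18, adjusted p = 0.000182, 19 of 20). The ephrin receptor Epha7 was 2.88-fold lower (-1.53 ± 0.27, adjusted p = 0.00157, 19 of 20). F7 (2.69-fold, 17 of 20), Akr1c13 (2.55-fold, 11 of 20) and Y-linked Eif2s3y (2.85-fold, 15 of 20) were higher, and the last 2 followed from a single cohort, MLL-GAS7 and MLL-AF9 respectively. Neutrophil granule genes were lower: Mmp8 2.97-fold (adjusted p = 0.00457, 16 of 20), Ltf 3.31-fold (0.031, 17 of 20), Olfm4 2.86-fold (0.0252, 19 of 20) and Fcnb 2.83-fold (0.0216, 17 of 20). Without the 5 arrays with the brightest hybridisation controls none of these 4 was called (adjusted p = 0.148, 0.301, 0.138 and 0.15), nor was F7 (0.158). Without MLL-GAS7_407 the adjusted p of Ltf, Olfm4 and Fcnb was 0.0824, 0.0739 and 0.061, and that of Ltf was also above the threshold without MLL-AF1p_803 (0.0516), MLL-GAS7_405 (0.0537) and MLL-GAS7_410 (0.0752) and MLL-AF9_301 (0.0577). Late neutrophil genes were lower in 4 of 18 (7 adjusted over the list alone, median -0.58, adjusted p = 9.77e-12, adjusted p = 0.179 with an estimated correlation) and MHC class II genes in 3 of 9 (4 adjusted over the list alone, median -0.44, adjusted p = 1.46e-07, adjusted p = 0.179 with an estimated correlation), with both lists called within each array set. Of the 2 cytoplasmic cohorts only MLL-GAS7 had more MHC class II expression than the other cohorts (median 1.27), and MLL-AF1p had less (-0.58). B cell (-0.16, adjusted p = 8.57e-05), monocyte (-0.14, 0.000155), stroma (-0.15, 0.0136), resident macrophage (-0.17, 0.0136), T and NK (-0.09, 0.0378) and interferon genes (-0.17, 0.038) shifted down, with adjusted p = 0.179, 0.313, 0.179, 0.313, 0.313 and 0.633 with an estimated correlation. Primary granule (0.23, 0.00215), ribosome biogenesis (0.20, 0.0251), DNA replication (0.18, 0.038) and oxidative phosphorylation genes (0.10, 0.043) shifted up, with adjusted p = 0.279, 0.633, 0.673 and 0.673 with an estimated correlation. Without MLL-GAS7_407 the B cell (adjusted p = 0.0947), resident macrophage (0.0947), stroma (0.19), T and NK (0.241), interferon (0.0947), ribosome biogenesis (0.148), DNA replication (0.148) and oxidative phosphorylation (0.218) calls were lost. In all, leaving out any 1 of 11 arrays ended the T and NK call, of 14 the interferon, of 15 the DNA replication, of 18 the oxidative phosphorylation and of 6 the ribosome biogenesis call, and MLL-AF1p_801 the stroma call (0.0578). Called members numbered 2 of 19 monocyte, 1 of 16 T and NK, 1 of 19 interferon and 2 of 9 primary granule genes, and 2, 1, 1 and 3 adjusted over the list alone, where 1 DNA replication gene was called too. Within array set 1 the monocyte (adjusted p = 0.421), resident macrophage, T and NK, interferon, DNA replication, ribosome biogenesis and oxidative phosphorylation lists were not called, and within set 2 the B cell (0.135), stroma (0.144), interferon (0.127), DNA replication (0.104) and oxidative phosphorylation (0.665) lists were not. After quantile normalization the stroma, resident macrophage, T and NK, interferon, ribosome biogenesis, DNA replication and oxidative phosphorylation calls were lost (adjusted p = 0.0778, 0.0838, 0.169, 0.167, 0.0536, 0.0838 and 0.169), with medians of 0.11, 0.11 and 0.03 for the last 3. Without the 5 arrays with the brightest hybridisation controls only the monocyte and primary granule lists among these 10 stayed called.

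In total 172 genes were higher and 50 lower with a nuclear partner, and higher genes made up 77.5% of the calls, against 58.2% with the values as deposited and 58.0% after quantile normalization. The total of 222 became 865, 104 and 112 without MLL-GAS7_406, _407 and _410, 121, 122, 349 and 138 without MLL-AF9_308, _301, _305 and _310, and 40 without the 5 arrays with the brightest controls. With the set as a term it was 308, within set 1 4 and within set 2 88, with 2 and 5 of the 10 genes named by size, Eif2s3y in both. Of the 10 possible divisions of the 5 cohorts into 3 and 2, 6 gave 222 genes or more.

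**Figure D4:**
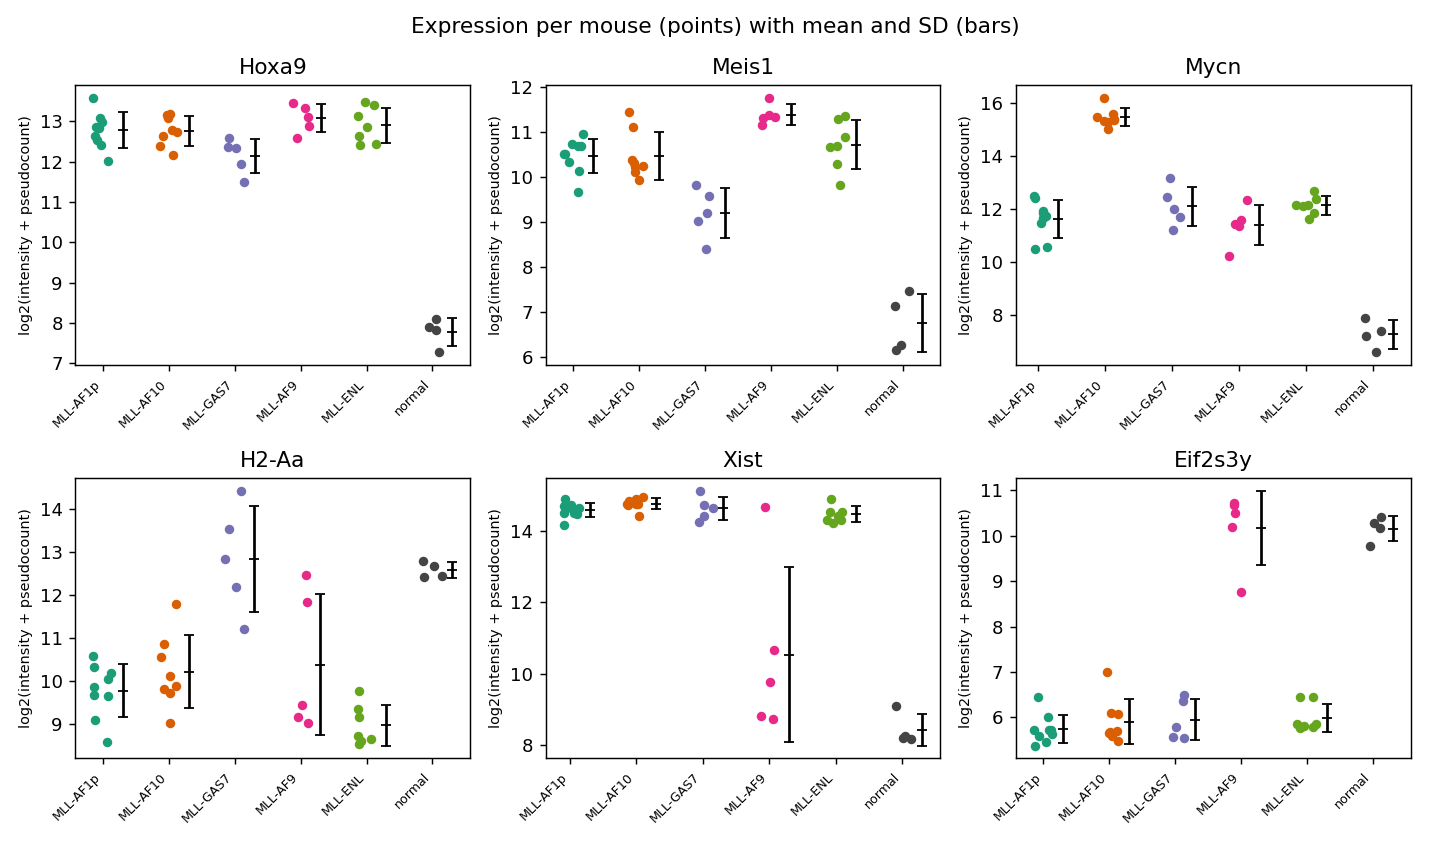
Expression of 6 genes (vertical axes, log2 of intensity plus pseudocount), 1 point per mouse, by cohort, with the mean and SD as bars. Hoxa9 and Meis1 are higher in every leukaemia than in normal marrow, Mycn is highest in MLL-AF10, H2-Aa is highest in MLL-GAS7, and Xist and Eif2s3y show opposite patterns with 1 MLL-AF9 mouse high in both.

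Mice of either sex were used, and the sex-linked genes followed the cohorts. Xist was high and the Y-linked genes low in all 29 MLL-AF1p, MLL-AF10, MLL-GAS7 and MLL-ENL mice, and the reverse held in all 4 normal samples and in 4 of 5 MLL-AF9 mice. MLL-AF9_305 carried both signals, with Xist at 14.67 and a Y-linked mean of 8.15 (log2). Neither these genes nor MLL-AF9 against others was separable from this pattern. Eif2s3y was 10.6-fold lower in leukaemia than in normal marrow, Kdm5d 2.66-fold and Uty 1.83-fold. The list of 4 had a median of -1.14 and a mean of -0.08 (1 higher and 3 lower on both counts, adjusted p = 0.0422, adjusted p = 0.088 with an estimated correlation), and its adjusted p was 0.0829 without MLL-AF9_305, 0.0551 without normal mouse 1, 0.0766 with the values as deposited and 0.0792 after quantile normalization. In MLL-AF1p (1 lower, with the adjusted p given above, lost without any 1 of 7 arrays and 0.125 without MLL-AF9_305, 0.0533 with the array set as a term and 0.117 and 0.207 within array sets 1 and 2), MLL-AF10 (2 lower, adjusted p = 0.0057, and 0.044 estimated, but 0.216 within set 1) and MLL-ENL (1 lower, adjusted p = 0.00792, adjusted p = 0.101 with an estimated correlation, and 0.0975 within set 2) the list also came out lower than the mean of the other 4 cohorts, which include the MLL-AF9 mice. Eif2s3y lay below the median of the other leukaemias in 7 of 9, 5 of 8 and 0 of 7 mice. Adjusted over the list alone, 1 was higher and 3 were lower in each of these 3 cohorts. Uty was 2.59-fold higher in MLL-AF9 than in the other cohorts (adjusted p = 8.08e-05). Without genes of the X and Y chromosomes 5418 genes differed between leukaemia and normal marrow and 1033 among the cohorts. Leaving these genes out does not remove a sex difference between the groups.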

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

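The tests of the sex of the mice, of RNA from another cohort in MLL-AF9_305 and of the array sets on Mycn were chosen after the result was seen, as were the array sets themselves. Each gene named by the rule was screened in each of the 6 groups for a mouse whose gap to the nearest other exceeded Dixon's 95% critical share of the range of its group. Of 348 sets of values for 58 genes, 36 passed, where chance alone gives about 1 in 20. In normal marrow (n = 4) the lone value was that of mouse 1 for Xist (0.914 of the range), Tmem212 (0.962) and Kdm5d (0.839), of mouse 3 for Car2 (0.901) and Rhag (0.907), and of mouse 4 for Bbx (0.862) and Eml5 (0.858). In MLL-AF9 (n = 5) it was that of MLL-AF9_307 for Sgip1 (0.739), Ppbp (0.726), Ikzf2 (0.791), Fnbp1l (0.811) and B4galt6 (0.8), of MLL-AF9_305 for Apoc2 (0.805), Tent5c (0.863) and Eif2s3y (0.732), of MLL-AF9_301 for Myof (0.906) and Gpnmb (0.745), and of MLL-AF9_308 for Hemgn (0.802). In MLL-GAS7 (n = 5) it was that of MLL-GAS7_407 for Ppbp (0.724) and Myof (0.862), of MLL-GAS7_408 for Tspan33 (0.798), and of MLL-GAS7_406 for Pdgfrb (0.718) and Dusp6 (0.853). In MLL-AF10 (n = 8) it was that of MLL-AF10_782A for Xist (0.556), MLL-AF10_798A for Mycn (0.533) and Rhag (0.612), MLL-AF10_797A for Alas2 (0.727), MLL-AF10_783A for Mmp8 (0.57), MLL-AF10_799A for Eif2s3y (0.582) and MLL-AF10_780A for Trp53i11 (0.551). In MLL-ENL (n = 7) it was that of MLL-ENL_741 for Sgip1 (0.604), MLL-ENL_760 for Alas2 (0.633), MLL-ENL_774 for Nkg7 (0.644) and MLL-ENL_701 for Rhoj (0.755). In MLL-AF1p (n = 9) it was that of MLL-AF1p_801 for Ak3 (0.651) and MLL-AF1p_805 for Tmem212 (0.544). Most mice per group came up for at most 2 genes, against 5 for MLL-AF9_307 and 3 each for MLL-AF9_305 and normal mouse 1.

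Of the 20 genes named for leukaemia against normal, 4 differed among the 5 cohorts by limma's F test over all genes. They were Xist (adjusted p = 4.75e-07), Mycn (1.1e-12), Penk (0.0486) and Meis1 (7.69e-05). In the control probe sets, which the gene comparisons did not use, the 3' to 5' actin ratio lay above the highest normal sample in 25 of 34 leukaemias and 18S signal in 24 of 34.

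Mycn was 3.65 (log2) higher in MLL-AF10 than in the other cohorts on 1 probe set. The 2 array sets are argued against as its source, since the smaller of the differences within them was 3.42. A change of the whole region is argued against by the 10 nearest measured genes, whose median difference was -0.0168. Cross-hybridisation or another transcript read by that probe set alone stays open, because the other kept Mycn probe set differed by 0.186 and averaged between 6.2 and 7.4 (log2) in each group. The one that the filter left out was as dim, at 7.02 in MLL-AF10 and 6.62 to 6.92 in the other groups. A higher level of Mycn message that the other probe sets cannot read stays open as well, and was not tested.

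Xist and the Y-linked genes showed 1 of 2 opposite patterns on 37 of 38 arrays, as cells of different sex in the groups would. That count restates the pattern, and the sex of the recipients was not told apart from that of the transplanted cells. The array that did not, MLL-AF9_305, carried both. Normal male marrow mixed into it is argued against: its erythroid genes stood at a share of -0.00335 of the normal level, while its Y-linked genes would need shares of 0.337 to 0.473. RNA of a female cohort may have been mixed in, but this was left undecided by a relative level of 0.497 for genes of MLL-AF9, which lies inside the range of 0.385 to 1.01 of the other 4 mice. Donor and recipient cells of different sex in 1 marrow stay open as a biological explanation that was not tested.

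The 2 array sets crossed all 5 cohorts, and the same 2 sets came out of every other gene. A technical difference in how probe sets read may explain them. The set's effect on 2 probe sets of a gene correlated with r = 0.262 across genes, which are not independent. This covers 572 genes called for the set among 3003 tested, not used to find the sets. The ratio to r for leukaemia against normal (0.774, 1802 genes) was 0.338. Sets found where probe sets of a gene disagree favour a low r, so it cannot decide against composition. Genes differed in median, MHC class II by 0.33 and late neutrophil by -0.199 (set 2 less set 1). Set 1, without normals, averaged a higher 3' to 5' actin ratio in every cohort (untested). No date or batch is given.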

How the results depend on the processing

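The array set as a term, each array set alone, leaving out the 5 arrays with the brightest hybridisation controls, and leaving out genes of the X and Y chromosomes were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Array set 1 holds no normal samples and gave no comparison with them, and the fit on only the arrays of the groups compared has no separate value for the mean of all cohorts. Dim genes are limited by signal over background: values near the pseudocount of 46.1 cannot show large changes, and changes under 2-fold were often missed on simulated data (32.8% called at 1.5-fold). Each leave-one-out fit kept the gene set and log values of the full data. The cause was not tested for any change below unless a cause is named.

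Apart from leaving out single arrays, the counts stayed within 1.5 times the reported value in 191 cases and moved further in 42. Under these settings calls of named genes held in 3077 cases, were lost in 339, reversed in 1 and gained in 5. List calls held in 1060 cases, were lost in 205, reversed in 4 and gained in 80, and in 5 more with the opposite sign. Of the 1060, the 2-fold limit and trended prior, which cannot alter list tests, gave 76 each. Leaving out single arrays, gene calls held in 8167 cases and were lost in 345. List calls held in 2737, were lost in 150, reversed in 1 and gained in 110, and 545 counts held and 25 moved.

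With the values as deposited the count against the other cohorts rose to 469 in MLL-AF1p and 79 in MLL-AF10. For MLL-AF10 it was 84 after quantile normalization, 25 with the mean of the probe sets and 68 with the median as pseudocount. Array weights gave 94 genes in MLL-AF10, 148 in MLL-AF9, 1360 in MLL-ENL, 414 for nuclear partners and 2031 in the F test. The added 2-fold limit lowered counts by its construction, to 1715 for leukaemia against normal and 1784, 1854, 1556, 1845 and 2106 for MLL-AF1p, MLL-AF10, MLL-GAS7, MLL-AF9 and MLL-ENL against normal. Against the other cohorts it left 57, 13, 168, 28 and 95 in that order, 30 for nuclear partners, 500 in the F test and 928 in all 5 cohorts. With an estimated correlation 9 lists were called for leukaemia against normal, not 18. Without probe sets that may read several genes, Ighm in MLL-AF1p against the others changed sign, to 0.202 (adjusted p = 0.536), because another probe set then stood for the gene.

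Each array set alone has fewer arrays, and the counts between cohorts fell. Against normal, within set 2, they rose to 5757 for all leukaemias and 5104 for MLL-AF10 and fell for the other 4 cohorts. Within set 1 they were 3, 7, 50, 20 and 60 for MLL-AF1p, MLL-AF10, MLL-GAS7, MLL-AF9 and MLL-ENL against the others, 4 for nuclear partners and 110 in the F test. Within set 2 they were 105, 4, 281, 9 and 71, then 88 and 249. Of the calls of named genes against other cohorts and of nuclear partners, set 1 kept 22 and lost 87. Set 2, which also gives the comparisons with normal, kept 152 and lost 72. List shifts that reversed within set 1 were those of monocyte genes in MLL-GAS7 (-0.176) and for nuclear partners (0.0844), and of ribosome biogenesis genes in MLL-AF9 (0.224, but -0.267 in set 2). Within set 2 they were, with set 1 second, late neutrophil (-0.389, 0.805), interferon (-0.00705, 0.398) and ribosome biogenesis genes (0.139, -0.352) in MLL-AF10, and DNA replication (-0.236, 0.189) and mitosis genes (-0.219, 0.219) in MLL-AF9. Without the 5 arrays with the brightest hybridisation controls the counts were 27 for MLL-AF10, 244 for MLL-GAS7 and 40 for nuclear partners, and the late neutrophil shift in MLL-GAS7 turned to -0.0523.

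Leaving out each array in turn, the counts ranged from 171 to 477 for MLL-AF1p, 14 to 49 for MLL-AF10, 317 to 1131 for MLL-GAS7, 30 to 57 for MLL-AF9 and 279 to 1168 for MLL-ENL against the others, and from 104 to 865 for nuclear partners. They ranged from 4549 to 5902 for leukaemia against normal, from 1904 to 2733 in all 5 cohorts and from 15 to 20 for the lists called in leukaemia against normal. In the F test it was at most 1531 and always within 1.5 times of 1078. Against normal they were 4008 to 5106, 4014 to 5059, 2827 to 4008, 3611 to 4680 and 4793 to 5710 for MLL-AF1p, MLL-AF10, MLL-GAS7, MLL-AF9 and MLL-ENL. The interferon shift in MLL-AF10 ranged from -0.0501 to 0.25, with the lowest without MLL-AF10_797A.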

Other observations

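The 5 cohorts shared the largest rises to different degrees. The enkephalin precursor Penk reached 12.36 ± 0.73 (log2, SD, n = 7) in MLL-ENL and 10.43 ± 1.34 (n = 8) in MLL-AF10, and Meis1 ranged from 9.20 in MLL-GAS7 to 11.39 in MLL-AF9, while Hoxa9 ranged only from 12.14 to 13.07 in the same 2 cohorts.

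The tests on other splits of the arrays and on other divisions of the cohorts were chosen before their results were seen. The comparisons were repeated with the arrays regrouped at random into groups of the same sizes, in 100 splits that include the real one. As many genes as in the real split were found in 1 of 100 for leukaemia against normal (real 5588, highest other 1085), MLL-AF1p against normal (4873, 3248), MLL-AF10 against normal (4873, 1852), MLL-AF9 against normal (4477, 3537) and MLL-ENL against normal (5523, 1945). It was 2 of 100 for MLL-GAS7 against normal (3613, 3726). In the F test among cohorts it was 1 (1078, 6), and for genes changed the same way in all 5 cohorts 1 (2504, 1). Against the other cohorts it was 1 for MLL-AF1p (311, 1), MLL-AF10 (41, 5), MLL-GAS7 (637, 7) and MLL-ENL (662, 5), and 2 for MLL-AF9 (49, 67). For nuclear against cytoplasmic partners it was 1 (222, 19). Chance in the grouping of the arrays was thus excluded for each of these at the level of 0.05. In single other splits the count exceeded the real one for MLL-GAS7 against normal and MLL-AF9 against the other cohorts, and the cause was not tested.

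The nuclear comparison did not single out the location of the partner. Of the 10 divisions of the cohorts into 3 and 2, 6 gave at least the 222 genes of the nuclear division, itself among them, and setting MLL-AF9 and MLL-ENL apart from the rest gave 820. The other 4 gave 113, 101, 22 and 13, so not every division yields as many. That differences between single cohorts, apart from location, gave the 222 genes stays open.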
